A study of Mus musculus with 11 samples.

How the data were processed

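ATF4 binding was profiled by CUT&RUN, in which an antibody directs micrococcal nuclease to cut and release the DNA beside its target protein in isolated nuclei. The cells were naive CD8+ T cells from the lymph nodes of female C57BL/6J mice, activated through CD3 and CD28 for 12 h or 48 h. Normal rabbit IgG libraries served as the background. Per the labels, the series held 11 libraries: 3 ATF4 and 4 IgG libraries at 12 h, and 3 ATF4 libraries and 1 IgG library at 48 h. Per the series design text, cells of 3 mice were pooled, so p-values and intervals given here say nothing about differences between animals. That text describes duplicates while the labels list 3 ATF4 libraries per time, and the labels were followed.

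The authors deposited 2 site tables, each listing the sites called higher in ATF4 than in IgG at a single time. Both hold positions and annotation alone, with 0 columns of values per library and no column of signal, fold, p or false discovery rate. Each site spans 401 bp and carries the nearest transcription start site (TSS), the distance to it and a class such as promoter, intron or distal intergenic. Per the submitters' processing notes, the tools were FastQC 0.12.1, Trim Galore 0.6.10, Bowtie2 2.5.1, SAMtools 1.17, Picard 3.2.0, deepTools 3.5.4, MultiQC 1.21, MACS2 2.2.9.1, DiffBind 3.12.0 and ChIPseeker 1.38.0, with the mouse build GRCm39. Their parameters, the thresholds behind the lists and any spike-in or exclusion list are not given in the sources used here. The sequencing depth of each library is unknown, and a site missing from a table was either not tested or not called. The number of listed sites moves with depth, with the control libraries and with the threshold, so the counts at the 2 times are not levels of binding.

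From these tables the sites were counted by deposited class, distance to the TSS, chromosome and nearest gene. A promoter site is one the deposited annotation places within 3 kb of a TSS. Coordinates are 1-based, on GRCm39, as deposited. Shares carry exact Clopper-Pearson 95% intervals, and differences in share carry Newcombe 95% intervals and Fisher's exact test, two-sided, adjusted by Benjamini-Hochberg over 16 comparisons. These intervals treat sites as independent and cover counting error only. Permutation tests used 100000 resamples. Shared sites overlapped by at least 1 bp and were set against 1000 random placements of the 48 h sites within the same chromosomes, from 3 Mb to the last site end, with a one-sided permutation p.

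Gene lists were tested with Fisher's exact test, two-sided, against 21900 protein-coding genes of a reference table of assembly GRCm38.p6, which supplied names, synonyms and gene types and no coordinates. Of the gene IDs in the tables, 373 of 374 at 48 h and 567 of 571 at 12 h were found there. The 19 lists held 300 hand-listed symbols, of which 299 matched, plus ribosomal protein and histone genes taken by symbol pattern. The lists covered amino acid synthesis, tRNA synthetases, amino acid transport, the integrated stress and unfolded protein response, other bZIP factors, autophagy, T cell activation, naive T cells, the cell cycle, mTORC1, glycolysis, oxidative stress, ribosomal proteins and histones. They also held markers of B cells, myeloid cells, CD4 and regulatory T cells, stromal and endothelial cells, and unrelated tissues. P-values were adjusted by Benjamini-Hochberg over the 19 lists, and the background held all protein-coding genes, expressed or not. The list test was tested on simulated data: 100% of planted lists were called at both times, and 0.167% at 12 h and 0.389% at 48 h of lists without a planted effect. Each planted list was given more members with a site than any of the 19 lists had in the data. The simulation used the gene counts of the nearest-gene rule alone. It therefore does not show power for the smaller counts seen or for promoter sites alone. The overlap count, run once between the 12 h sites and a random placement of the 48 h sites, found 30 of 30 planted overlaps.

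The lists, tests and rule for naming genes were fixed before the data were examined. The rule names each list member assigned to a site, and the sites present at both times. Its other parts, which rank by fold or false discovery rate or need a motif match, could not be applied to tables without those values. Genes outside the rule are said to have been chosen after the tables were read. Predicted genes and pseudogenes were only counted. A further 11 gene families were formed and tested after the tables were read, and the result of 1 of them is not reported here. Also not run were thresholds stricter than the authors', the fold at shared sites, and comparisons that leave out or pair replicates. The motif search, the annotation recomputed from a reference and random regions matched on distance to the TSS needed a GRCm39 genome, which was not used here, so the random placements kept chromosome and width alone. Software was Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.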

Results

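ATF4, a bZIP transcription factor of the integrated stress response, was mapped by CUT&RUN in activated mouse CD8+ T cells at 12 h and 48 h, with IgG libraries as background. The labels give 3 ATF4 libraries per time, 4 IgG libraries at 12 h and 1 at 48 h. All sites below come from the authors' deposited tables of sites higher in ATF4 than in IgG. The depth per library is unknown, and no replicate spread can be given because the tables hold no value per library.

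The first question was where ATF4 sites lay at each time. At 12 h, 612 sites were listed beside 571 nearest genes, and most were far from promoters. Distal intergenic regions held 310 sites (50.7%, 95% interval 46.6 to 54.7), introns held 224 (36.6%, 32.8 to 40.6) and promoters 52 (8.50%, 6.41 to 11.0). At 48 h, 376 sites were listed beside 374 nearest genes, and promoters held 229 of them (60.9%, 55.8 to 65.9). Distal intergenic regions then held 72 (19.1%, 15.3 to 23.5) and introns 59 (15.7%, 12.2 to 19.8). Among sites outside promoters, introns held 40.1% at 48 h and 40.0% at 12 h.

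The promoter share was 52.4 percentage points higher at 48 h than at 12 h (95% interval 46.8 to 57.6; Fisher's exact p = 2.09e-71, adjusted p = 1.11e-70). Sites that held a TSS made up 49.2% of the list at 48 h and 2.78% at 12 h. The median distance to the nearest TSS was 30 bp at 48 h and 35290 bp at 12 h. Among sites outside promoters the medians were 30356 bp at 48 h and 42956 bp at 12 h, a difference that did not pass a two-sided permutation test (p = 0.0775). The share of these sites over 50 kb from a TSS was 32.7% at 48 h and 46.6% at 12 h. That difference passed Fisher's exact test (adjusted p = 0.0109 over 4 comparisons added after the tables were read). The promoter share was higher at 48 h on 20 of the 20 chromosomes with sites at both times. The times differ in IgG libraries, 4 against 1, so the time and the control set cannot be separated in this comparison.

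**Figure D1:**
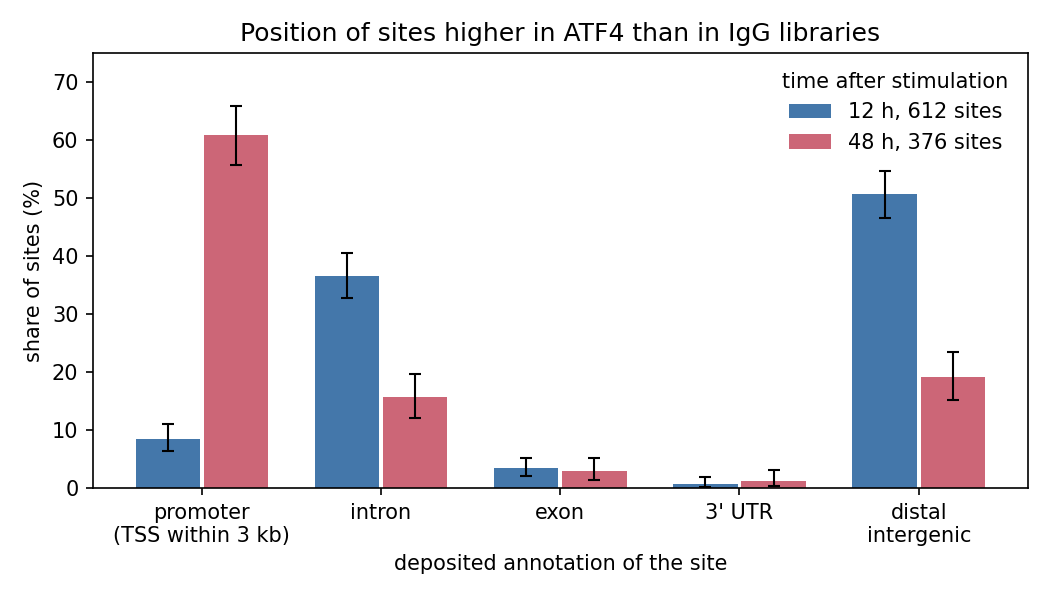
Share of listed sites (percent, vertical axis) in each deposited annotation class at 12 h (blue, 612 sites) and 48 h (red, 376 sites); bars are shares and lines are exact 95% intervals for counting error. Promoters held 8.50% of sites at 12 h and 60.9% at 48 h, while distal intergenic regions held 50.7% and 19.1%.

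Promoter sites at 48 h sat close to the TSS. Of the 217 sites annotated within 1 kb, 190 had their centre within 250 bp of the TSS (87.6%, 82.4 to 91.6), and the median centre lay at -60 bp. At 12 h, 20 of 33 such sites did (60.6%, 42.1 to 77.1), with a median of -2 bp. The shares differed by Fisher's exact test, two-sided (p = 3.92e-04), a test chosen after the tables were read.

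**Figure D2:**
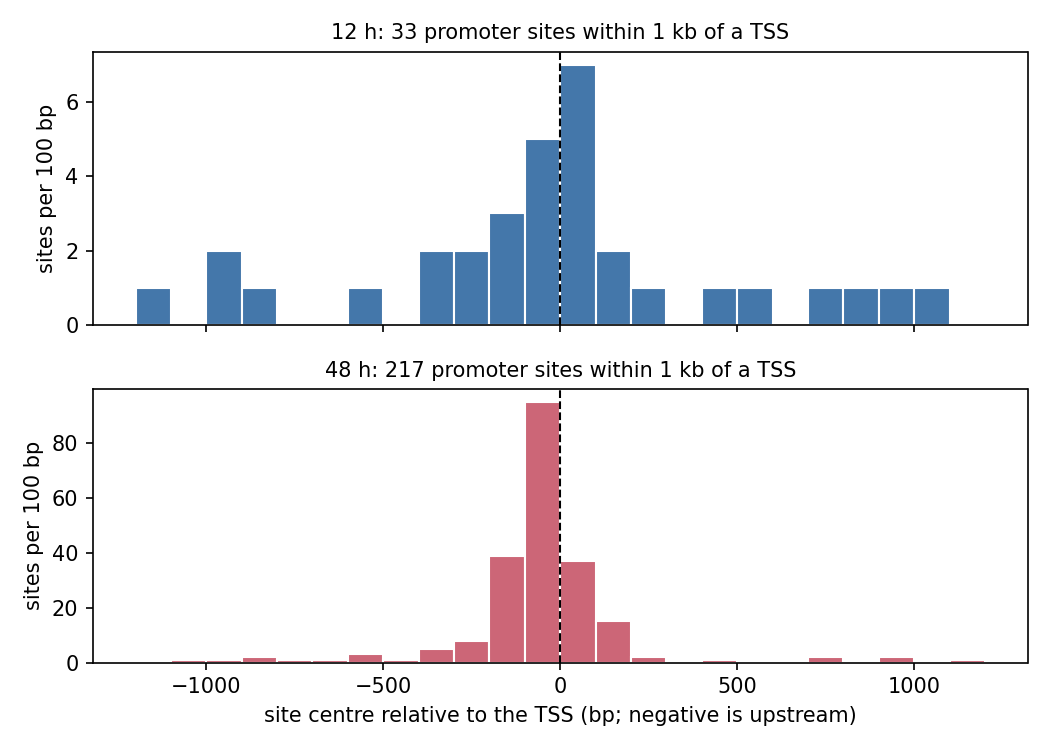
Number of sites per 100 bp (vertical axis) by position of the site centre relative to the nearest TSS in bp (horizontal axis, negative upstream), for promoter sites within 1 kb at 12 h (upper, 33 sites) and 48 h (lower, 217 sites); the dashed line is the TSS and the vertical scales differ. The 48 h sites gather around a median of -60 bp.

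The type of the nearest gene differed between the lists, in part along with the promoter share. Protein-coding genes were nearest to 311 of 376 sites at 48 h (82.7%) and 365 of 612 at 12 h (59.6%), a difference of 23.1 points (17.4 to 28.3; Fisher's exact p = 9.45e-15, adjusted p = 2.52e-14). At promoters it was 212 of 229 at 48 h and 41 of 52 at 12 h, which was not tested. Outside promoters it was 99 of 147 at 48 h (67.3%) and 324 of 560 at 12 h (57.9%), with Fisher's exact p = 0.0379 and adjusted p = 0.0759 over 4 comparisons added after the tables were read. Long non-coding RNA genes were nearest to 38 sites at 48 h (10.1%) and 146 at 12 h (23.9%). Small RNA genes were nearest to 22 (5.85%) and 90 (14.7%). At 12 h, 35 genes had more than 1 site, and at 48 h only 2 did. The spread of sites over the chromosomes differed between the times (permutation p = 0.0409, a test outside the plan). The common odds ratio for a promoter position within chromosomes was 16.3 (95% interval 11.3 to 23.3).

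**Figure D3:**
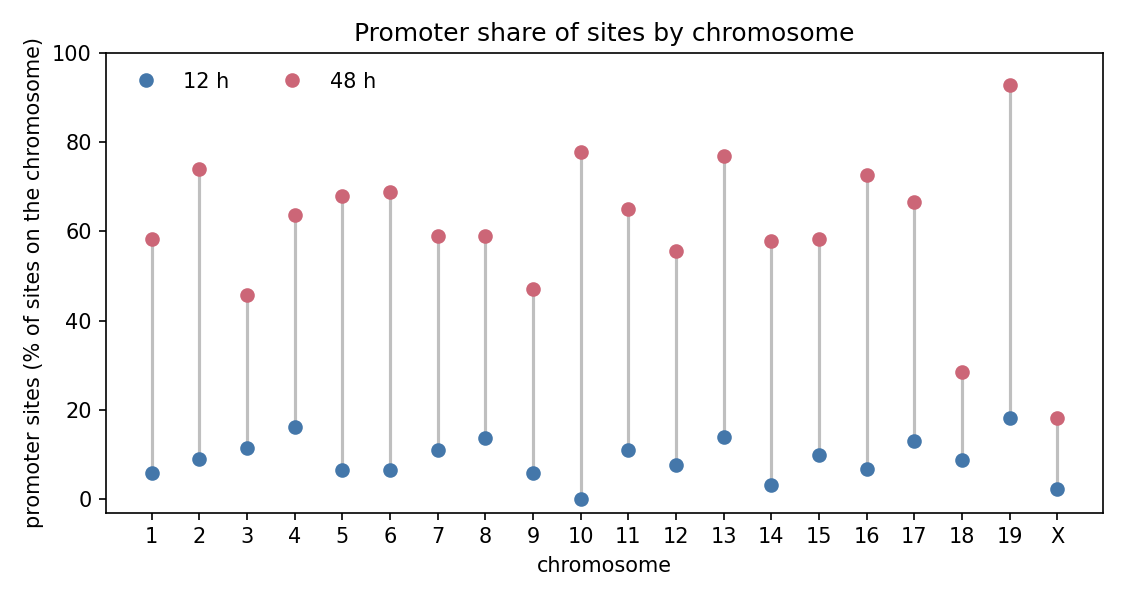
Promoter sites as a percent of all listed sites on each chromosome (vertical axis) at 12 h (blue) and 48 h (red), with a grey line joining the times. The red point lies above the blue on all 20 chromosomes shown, and no error is drawn.

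The next question was whether the same sites and genes were listed at both times. A single site overlapped, at the promoter of Mios, which encodes a part of the GATOR2 complex that relays amino acid supply to mTORC1. It spanned chromosome 6, 8209020 to 8209420, at 12 h and 8209024 to 8209424 at 48 h, a 397 bp overlap with both centres 2 bp from the TSS. Random placement gave a mean of 0.064 overlaps, and 1 or more arose with a one-sided permutation p of 0.0599. At 50% reciprocal overlap that p was 0.0360, and with centres within 500 bp it was 0.0729, so the call depended on the overlap required. The random sites were not matched on distance to the TSS.

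By nearest gene, 10 protein-coding genes were listed at both times, against 4.91 from independent lists of 347 and 310 genes (odds ratio 2.10, Fisher's exact p = 0.0335). They were Mios, Arhgap29, Arhgap24, Celf4, Cyp4b1, Hnf4g, Magi2, Nrp2, Olfm4 and Wwc1. Among them is Nrp2, a semaphorin and VEGF co-receptor. Its 48 h site lay in intron 22 of Pard3b, at -68875 bp from the Nrp2 TSS. Celf4, an RNA-binding protein gene, had sites in its 3' UTR on chromosome 18 at both times, 1511 bp apart. At promoters alone the shared genes were Mios and Arhgap29, 2 against 0.387 from independent lists (Fisher's exact p = 0.0572). The Arhgap29 sites lay apart, on chromosome 3 at 121745148 to 121745548 at 12 h and 121761168 to 121761568 at 48 h. The test treats genes as equally easy to hit and was not matched on gene length.

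The fixed gene lists addressed which known groups lay beside ATF4 sites at 48 h. None of the 19 lists passed the adjusted threshold of 0.05, whether sites were assigned by nearest gene, promoter or host gene. By nearest gene, only the other bZIP factors passed an unadjusted 0.05. They had 3 of 26 members with a site against 0.368 from chance, with Fisher's exact p = 0.00574 and adjusted p = 0.109. These were Dbp, a circadian activator, at its promoter (chromosome 7, 45354148 to 45354548), Bach2, which restrains effector differentiation, in intron 1 (chromosome 4, 32290977 to 32291377), and Fos, an AP-1 subunit, at -18329 bp from its TSS.

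Cell cycle genes had 2 of 36 members with a site, the promoters of Mcm2 (chromosome 6, 88875573 to 88875973) and Mcm4 (chromosome 16, 15455117 to 15455517). Both encode subunits of the replicative DNA helicase. The Fisher's exact p was 0.0919 by nearest gene (adjusted p = 0.873) and 0.0474 by promoter (adjusted p = 0.900). Of 19 matched cytosolic tRNA synthetase genes, 1 had a site: Mars1, which charges methionyl-tRNA, at its promoter on chromosome 10, 127147424 to 127147824. Ribosomal protein genes had 2 of 85, at the Rpl9 promoter and 318316 bp from Rps15a. Histone genes had 2 of 72, at the H4c14 and H2ac11 promoters, and reads from such near-identical copies are uncertain. Naive T cell genes had 1 of 13, Foxp1, which maintains T cell quiescence, at 81857 bp.

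At 48 h the remaining 13 lists had no member with a site by nearest gene. They included amino acid synthesis (18 genes), amino acid transport (14), the stress and unfolded protein response (24), T cell activation (28), mTORC1 (22), autophagy (14), glycolysis (18) and oxidative stress (12). Chance gives 0.0991 to 0.396 genes for each of these 13 lists, so their zeros cannot show a shortage of listed sites. The zeros bound the share of members with a listed site from above, and only loosely. The exact intervals reached 14.2% for the stress and unfolded protein response and 18.5% for amino acid synthesis. Across the 13 lists the upper ends ran from 12.3% (T cell activation) to 41.0% (CD4 and regulatory T cell markers). The markers of other cells were also without sites, with 10 B cell, 10 myeloid, 7 CD4 or regulatory T cell, 10 stromal and 18 unrelated tissue genes. A gene missing from the table was not called, which does not show that it was unbound.

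At 12 h, no list passed the adjusted threshold, and 3 of the 19 had a member with a site by nearest gene, none at an unadjusted p under 0.05. Slc7a11, the cystine and glutamate exchanger, had a site in its 3' UTR (chromosome 3, 50324133 to 50324533), 73527 bp from the TSS. Ccr7, the receptor that guides T cells to lymph nodes, had a promoter site 1791 bp from the TSS (chromosome 11, 99043712 to 99044112). At promoters alone the naive T cell list, through Ccr7, had an unadjusted Fisher's exact p of 0.0235 and an adjusted p of 0.446. The third gene was Rpl10l, at 49799 bp. The remaining lists had 0 members with a site by nearest gene, where chance gives 0.111 to 1.14 each.

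Taking the amino acid synthesis, tRNA synthetase, transport and stress response lists as a group of 75 genes, each time had 1 gene with a site by nearest gene (1.33%, 0.0338 to 7.21). Those genes were Mars1 at 48 h and Slc7a11 at 12 h, against 1.06 and 1.19 from chance. At promoters alone, 1 of the 75 genes had a site at 48 h against 0.726 from chance, and 0 had a site at 12 h against 0.137, too few to show a shortage.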

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

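The tests of explanations in this part were all chosen after the tables were read, the within-chromosome and protein-coding tests before their own results were seen and the overlap and control-number tests after. The 48 h list differed from the 12 h list in position by Fisher's exact test of the difference itself. The promoter share was 52.41 points higher at 48 h, and the share with a protein-coding nearest gene was 23.07 points higher. The intron share differed by -20.91 points, the distal intergenic share by -31.5 points and the share over 50 kb from a TSS by -29.88 points. The intron and distal intergenic differences follow in large part from the promoter share, and the protein-coding difference in part. Among sites outside promoters the intron difference was 0.136 points and the distal intergenic difference -6.38 points. The protein-coding difference there was 9.49 points, and none of these passed an adjusted 0.05. The difference over 50 kb was then -13.95 points (Fisher's exact adjusted p = 0.0109 over 4 comparisons). The share on chromosome X differed by -3.94 points (Fisher's exact adjusted p = 0.0121 among the classes, 0.175 among the chromosomes).

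For the promoter share, the tables argue against 3 narrow technical explanations, none of which concerns depth, threshold or the controls. A different spread over chromosomes would bring the within-chromosome odds ratio to 1, and it was 16.25 (95% interval 11.32 to 23.32). That outcome was largely fixed beforehand, since the share was higher at 48 h on all 20 chromosomes with sites at both times. More sites beside non-coding genes at 12 h would remove the difference among sites with a protein-coding nearest gene, where it was 56.93 points (50.44 to 62.62). Extra sites at 12 h that diluted the same promoter sites would leave most of the 12 h promoter sites shared, and 1.923% were (0.04868 to 10.26). The counts of promoter sites, 52 at 12 h and 229 at 48 h, already went against dilution, so this overlap adds little. The number of IgG libraries stays open, since 12 h had 3 more than 48 h and the tables used here hold no value per library to equalise them. Weak control subtraction at accessible promoters at 48 h and a change in ATF4 binding with time cannot be told apart. Nor can a difference in depth or threshold between the times, or a larger share of background sites at 12 h. None of these was tested, and the 12 h shares were not set against random regions.

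A site was listed on chromosome Y at 48 h, 1 of 376, in cells of mice given as female. It lay at 90813830 to 90814230, in intron 3 of Erdr1, nearest to Erdr1x. Erdr1 lies in sequence shared by X and Y, so such a site need not come from a Y chromosome.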

How the results depend on the processing

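The alternatives marked here as added were chosen after seeing the data. The promoter difference kept its direction and its side of the threshold in 4 alternatives, from 46.4 points for sites that hold the TSS (added) to 56.9 points for sites nearest a protein-coding gene (added). Outside promoters (added), the intron difference reversed to 0.136 points and the distal intergenic difference no longer passed (-6.38 points), since promoter sites leave the denominator. Site counts without chromosome Y were 375 at 48 h and 612 at 12 h. The shared-site count was 1 at 50% reciprocal overlap, which then passed the threshold (permutation p = 0.0360), 1 with centres within 500 bp, which did not pass (permutation p = 0.0729), and 2 within 5 kb (added, permutation p = 0.259). The count stayed at 1 under the 1 bp, 50% and centre rules, with the Mios site each time. The random mean was 0.064, 0.037 and 0.077 in that order, so the call moved with the random mean alone. The shared-gene count was 2 at promoter sites alone, no longer past the threshold (Fisher's exact p = 0.0572), where fewer genes enter, and 14 by nearest or host gene (added, exact p = 0.00220). The count of lists past the adjusted threshold was 0 under every gene assignment run. No paired analysis was possible because the tables hold no value per library, and leaving out replicates was not run for the same reason. Stricter thresholds and the fold at shared sites need columns the tables lack. The motif share, recomputed annotation and TSS-matched random regions were not run without a GRCm39 genome. Depth is unknown, so no limit can be set on sites that were missed.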

Other observations

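The genes, families, symbol stems and order of sites in this part were examined only after the tables were read, while the overlap of promoter genes was planned. The overlap was set against chance as an explanation only after its result was seen. Promoters listed at 48 h included those of Sesn1 and Sesn3, stress-inducible regulators of mTORC1, and of Ppp1r15b, which directs dephosphorylation of eIF2alpha. They also included Sqle, Fdft1 and Dhcr7, enzymes of cholesterol synthesis, and Fasn, the fatty acid synthase. Immune genes with a 48 h promoter site included Cd86, whose site held the TSS, and Rac2, whose site lay 928 bp from it. At 12 h, promoter sites lay at B2m, the shared light chain of MHC class I, at Birc3, an inhibitor of apoptosis, and at Tfeb, a regulator of lysosomal genes. None of these 12 h sites held the TSS, with distances of 895 bp for B2m, 1494 bp for Birc3 and -1974 bp for Tfeb.

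Olfactory receptor genes had no promoter site at 48 h, 0 of 1110 against 10.7 from chance, the only family called among 1431 families of shared symbol stem at 48 h promoters (Fisher's exact adjusted p = 0.0365). At 12 h they had 4 of 1110 against 2.03 from chance at promoters (exact p = 0.143), 10 against 17.6 by nearest gene (exact p = 0.0634) and 10 against 19.8 by nearest or host gene (exact p = 0.0194, adjusted p = 0.107). The background held all protein-coding genes, expressed or not. No background of expressed genes or of promoters was used, so the zero at 48 h cannot be credited to ATF4.

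Of the 11 families tested, 6 had more 48 h promoter sites than chance by Fisher's exact test. The families were formed after the list was read, so such an excess was partly built in. The amino acid sensing family had 3 of 17 members (Mios, Sesn1 and Sesn3, exact adjusted p = 0.003026) and the cholesterol family 3 of 21 (exact adjusted p = 0.00375). The MCM helicase had 2 of 6 (Mcm2 and Mcm4; exact adjusted p = 0.00375). Splicing and hnRNP genes had 3 of 53 (exact adjusted p = 0.0323), Rab GTPases 3 of 59 (exact adjusted p = 0.0358) and Trim genes 3 of 68 (exact adjusted p = 0.0445). By nearest gene the splicing, Rab and Trim families no longer passed, with exact adjusted p of 0.0861, 0.0937 and 0.113. Olfactory receptors had fewer than chance, as above. Oxidative phosphorylation subunits had 3 of 92, mitochondrial ribosomal proteins 1 of 78 and Zfp genes 3 of 397, none past the threshold (exact adjusted p = 0.0826, 0.651 and 1). At 12 h by nearest gene, the sensing family had 2 of 17 (Bmt2 and Mios; exact p = 0.0291, adjusted p = 0.160). The cholesterol, MCM, splicing, Rab and Trim families then had 0, where chance gives 0.0951 to 1.08 each.

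The families were assembled around genes already seen in the list, so these p-values are too small and chance may account for any of them, including the 0.003026 of the sensing family. Their background also held all protein-coding genes, expressed or not, so an excess over it cannot be credited to ATF4. In the scan of 1431 symbol stems, which was not built on the hits, the sestrins had 2 of 3 members and an exact adjusted p of 0.199, and the Mcm and Rab stems had an exact adjusted p of 1.

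The pair of promoter genes listed at both times could be chance, since independent lists gave an exact p of 0.05722.

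In the order of the deposited 12 h table, promoter sites came later than other sites, at a mean position of 398 against 298 (permutation p = 1.40e-04). The last sixth of that table held 21 promoter sites of 102 (20.6%), against 31 of 510 (6.08%) before it. At 48 h the permutation p was 0.437. The quantity behind the order is not given in the sources used here.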
